A study of Mus musculus with 7 samples.

How the data were processed

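The series holds 7 RNA libraries of F4/80-positive macrophages sorted from Lewis lung carcinomas, 3 of mice with a myeloid deletion of Dicer1 and 4 of control mice. The labels state an RNA integrity number above 7 for all samples. Per the labels, cDNA was amplified from 2 ng of total RNA with the SMARTer ultra low kit, libraries were made from 1 ng of cDNA with Nextera XT, and read pairs of 50 nt per mate were sequenced on a HiSeq instrument. The protocol keeps no strand, so reads of genes that overlap on opposite strands are not separated.

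The deposited files give, per gene and library, counts of uniquely placed reads. Per the file headers they also hold expected counts, which add fractional shares of reads placed on several genes, and RPKM values, computed by the authors with lengths and totals that are not stated. The processing notes name Bowtie2 without a version. The genome build, annotation and counting tool are not given in the sources used here. All unique counts were even in all 7 libraries, so both mates of a pair were counted as 2 reads. The 3 count columns fitted together within 0.03 reads. The RPKM values were not used.

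The files listed 24084 genes in at least 1 library and 16343 in all, and the 31124 unlisted values were set to 0. Ensembl IDs were matched to symbols, positions and 3' UTRs of GENCODE mouse release 21 (GRCm38), with 21813 IDs matched and 2271 left without a symbol. Depth ranged from 43.0 to 51.2 M uniquely placed reads. With PCR amplification and no molecular identifiers, reads are not independent molecules, so depth overstates the precision. The common dispersion was 0.203, a biological coefficient of variation of 45.1%, which limits the precision more than depth.

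Dicer1-deleted libraries were compared with control libraries in edgeR 4.0.16 (R 4.3.3) on the unique counts, with filterByExpr (16226 genes kept), TMM scaling, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Fold changes are Dicer1-deleted minus control on the log2 scale, and CPM values are TMM-scaled. The median log2 fold change of all genes was 0.03, and no scaling moved it by over 0.1. No covariate was used. The groups, tests, gene lists, alternatives and rule for named genes were set before the data were examined. That rule takes Dicer1, and the 10 largest rises and 10 largest falls among calls without overlap between groups and with a mean of at least 5 CPM, leaving out predicted genes, with up to 4 called members per list. As edgeR called 4 genes, the same rule was applied to the calls of DESeq2 1.42.0 and to list members that passed when adjusted over their list alone, a choice made after the values were seen. Some edgeR calls and uncalled markers are named outside the rule, also after their values were seen, and not every gene that meets it is named.

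The 35 gene lists were tested with camera of limma 3.58.1 on the signed statistics of the fit, with a preset correlation of 0.01 and, beside it, an estimated correlation and fry. They were adjusted over the 35 lists. The mean log2 CPM of each list was compared by an exact permutation test over the 35 splits of 7 libraries into 3 and 4. For the seed-site test, 20 microRNAs of myeloid cells and 6 of other tissues were searched in the longest annotated 3' UTR of 12127 genes. Log2 fold changes were taken relative to the median of bins, crossing 10 bins of UTR length with 10 of expression. The shift was their median over genes with a site, less its mean over 100000 permutations of site labels within bins (two-sided p). Principal components were computed from log2 CPM with a prior count of 1. The length trend of each library was a lowess of its log2 ratio to the mean of all 7 libraries on transcript length. This length was known for 94.4% of tested genes.

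The workflow was tested on simulated data with 200 changed genes among 16226, and with a shift of 0.3 put on the sites of 1 microRNA, of which 0.248 was found with 0 other microRNAs called. Alternatives set beforehand were other size factors, no TMM factors, DESeq2, limma-voom, robust dispersion, no filter, a filter of 10 CPM in 3 libraries, the L code of the titles as covariate, a fold threshold (glmTreat), scaling without the 20 most abundant genes, leaving out each library, other list tests, other site definitions and other inputs to the principal components. Added after seeing the data were read pairs in place of reads, multiply placed reads, a transcript length correction, limma-voom with sample quality weights, edgeR's newer quasi-likelihood, DESeq2 without Dicer1-deleted replicate 2, camera on log2 CPM and the site test without each library. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the site test and tables.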

Results

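RNA was measured in tumor-associated macrophages, sorted as F4/80-positive cells from Lewis lung carcinomas, tumors of a mouse lung cancer line grown under the skin. In 3 libraries the mice lacked Dicer1 in myeloid cells, through a Cre recombinase expressed from the lysozyme M locus. The 4 control libraries came from mice with the same Cre and an intact Dicer1. Dicer1 encodes the ribonuclease that cuts microRNA precursors into mature microRNAs. The comparison addressed how the loss of Dicer1 alters the activation state of macrophages in a tumor. The Dicer1-deleted libraries held 47.0, 45.4 and 44.6 M uniquely placed reads and the control libraries 47.1, 46.4, 51.2 and 43.0 M, with both mates of a pair counted. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries.

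Dicer1 was lower in every Dicer1-deleted library than in every control library. Its level was 7.85, 6.86 and 7.86 counts-per-million (CPM) in the 3 Dicer1-deleted libraries and 15.7, 15.8, 18.6 and 17.1 CPM in the 4 control libraries, a log2 fold change of -1.16 ± 0.23 (SE). The mean went from 16.8 ± 1.35 to 7.52 ± 0.572 CPM (SD, n = 4 and 3). In edgeR the adjusted p over all genes was 0.150, and in DESeq2 it was 4.96e-05. Dicer1 lies on chromosome 12 at 104687742 to 104751952 of the GRCm38 reference. The conditional allele removes only part of the gene, so reads from the rest remain countable and the level is a weak check of the labels.

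**Figure D1:**
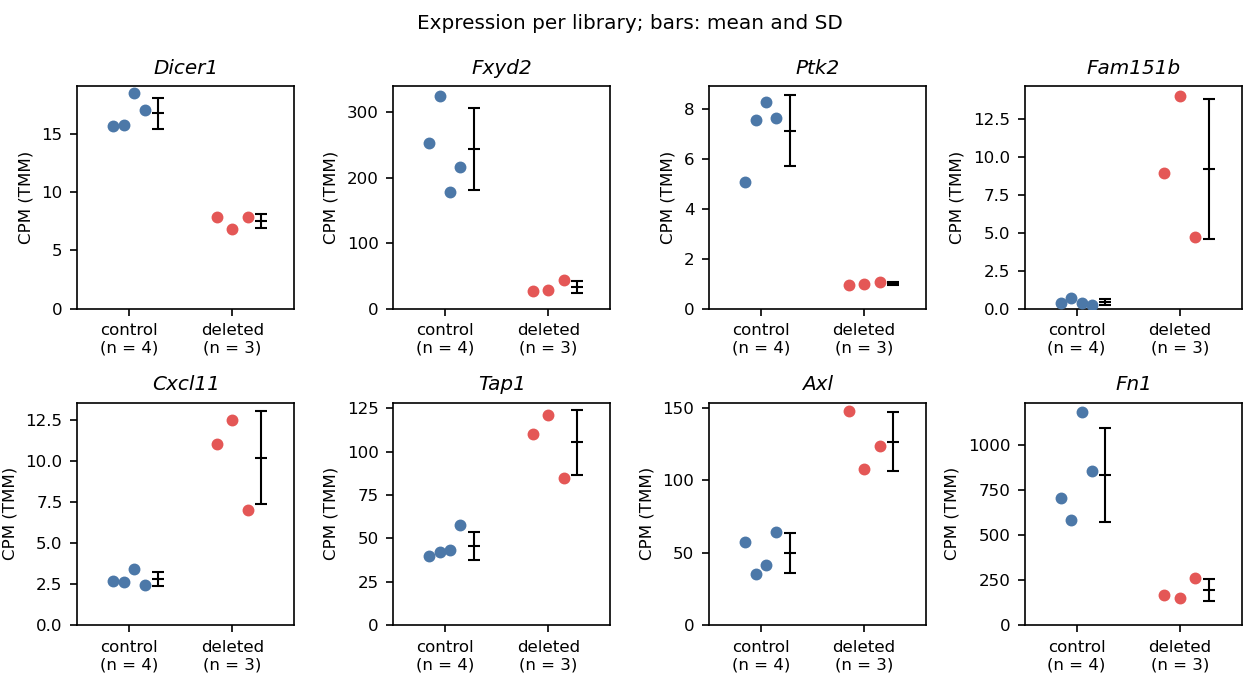
Expression per library in TMM-scaled CPM (vertical axes from 0; points, libraries; bars, mean and SD) of Dicer1, 3 genes past the edgeR threshold and 4 members of fixed gene lists. In each panel the 3 Dicer1-deleted and the 4 control libraries do not overlap, for Dicer1 at 6.86 to 7.86 against 15.7 to 18.6 CPM.

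Of the 16226 genes tested in edgeR, 4 passed an adjusted p of 0.05, and 3 of these fell. Fxyd2, a regulatory subunit of the sodium pump, fell from 244 ± 62.6 to 33.0 ± 8.91 CPM (SD, n = 4 and 3), a log2 fold change of -2.88 ± 0.34 (SE, edgeR adjusted p = 0.0378). Ptk2, which encodes the focal adhesion kinase, fell from 7.13 ± 1.41 to 0.996 ± 0.0621 CPM, with a log2 fold change of -2.83 ± 0.33 (SE). Fam151b rose from 0.422 ± 0.209 to 9.21 ± 4.62 CPM, a log2 fold change of 4.44 ± 0.51 (SE). Ptk2 and Fam151b had the same edgeR adjusted p as Fxyd2, and they are named although their mean level kept them outside the fixed rule for named genes. No gene passed without Dicer1-deleted replicate 1, without any single control replicate, or with the L code of the titles as covariate. Without Dicer1-deleted replicates 2 and 3, 3 and 2 genes passed, of which 1 and 2 were among the 4.

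In DESeq2 405 genes passed the same threshold, 150 higher and 255 lower in Dicer1-deleted macrophages. The genes named next followed the fixed rule applied to the DESeq2 calls, a choice made after the values were seen. Dnase1l3, a secreted nuclease, rose from 9.96 ± 8.60 to 249.5 ± 88.7 CPM (SD, n = 4 and 3). The iron exporter Slc40a1 rose from 88.0 ± 71.9 to 1076 ± 776 CPM, with 224 CPM in Dicer1-deleted replicate 2. Treml4, a receptor of myeloid cells, rose from 20.98 ± 11.6 to 198 ± 71.6 CPM. The phosphatase Dusp2, the adaptor Scimp, the protease inhibitors Spint1 and Serpina3g, the receptor F2rl2 and the transcripts AW112010 and Slc36a3os were the other rises. Among the falls, the protease cathepsin K (Ctsk) went from 1769 ± 1476 to 96.5 ± 38.9 CPM, and Atp6v0d2, a subunit of the proton pump of lysosomes, from 438 ± 343 to 42.2 ± 7.84 CPM. Lyve1, a hyaluronan receptor of resident macrophages, fell from 56.9 ± 45.6 to 3.08 ± 2.53 CPM. Cxcl13, a chemokine that attracts B cells, and Kbtbd11, Ephx1, Klk8, Ccr7 and Slc9a4 also fell. For these 19 genes, none called by edgeR, DESeq2's adjusted p lay between 1.53e-10 and 0.0199 and edgeR's between 0.105 and 0.352. Without Dicer1-deleted replicate 2, AW112010, Slc36a3os and Ccr7 no longer passed in DESeq2, with adjusted p-values of 0.407, 0.0514 and 0.116. The DESeq2 log2 fold change went from 2.76 to 1.27 for AW112010 and from 2.62 to 1.63 for Slc36a3os, while that of Ccr7 was as large, at -3.21 with all libraries and -3.66 without this one. F2rl2 and Slc36a3os overlap Iqgap2 and Slc36a3 on the opposite strand, and this unstranded kit does not separate their reads.

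On simulated counts with the spread of these libraries, edgeR recovered 29 of 50 genes changed 4-fold and 1 of 50 changed 2-fold. DESeq2 recovered 43 and 7 of 50, and 24.8% of its calls were genes that had not been changed, against 5.95% of edgeR's. The simulation drew genes independently, changed only genes of at least 5 CPM, and held no library that stood apart and no trend with transcript length. The real libraries had such a library and such trends, so these rates need not hold for them. At an unadjusted p under 0.05 edgeR listed 1300 genes. The values of the groups did not overlap for 1510 of the 16226 genes, or 9.31%, where chance gives 5.71%.

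Genes induced by interferon-gamma were higher in Dicer1-deleted macrophages as a group. Of 38 tested members of the list of interferon-gamma targets, 36 had a positive log2 fold change, and the median was 0.80. No member passed edgeR over all genes, 13 rose when adjusted over the list alone, and 10 rose in DESeq2. Cxcl11 and Cxcl10, chemokines that attract T cells, rose from 2.79 ± 0.439 to 10.2 ± 2.85 CPM and from 214 ± 18.98 to 575 ± 230.1 CPM (SD, n = 4 and 3). Tap1, a peptide transporter of antigen presentation, rose from 45.6 ± 8.12 to 105 ± 18.7 CPM, and Il12rb1, a chain of the interleukin 12 receptor, from 0.146 ± 0.123 to 5.22 ± 4.83 CPM. Serpina3g, at -0.45 Mb from Dicer1 and a member of a family of close copies, rose from 13.3 ± 5.96 to 83.0 ± 28.8 CPM. The list passed in camera at a preset correlation of 0.01 (limma, adjusted p = 6.51e-20), and had an adjusted p of 0.270 with an estimated correlation. Its mean log2 CPM was higher in each of the 3 Dicer1-deleted libraries than in every control library, with an exact permutation p of 0.0571, and 0.375 when adjusted over the 35 lists. Cxcl10 and Cxcl11 overlap Art3 on the opposite strand, and Fn1 and Il27 overlap Apol7d and Apobr. The list of type I interferon-stimulated genes had 21 of 36 members above 0, a median of 0.18 and an adjusted p of 0.249, and its call depended on the fit. It passed with the L code as covariate (median 0.51, adjusted p = 9.53e-06), with quality weights (0.41, adjusted p = 0.00552), without Dicer1-deleted replicate 2 (0.24, adjusted p = 0.0443) and without control replicate 3 (0.49, adjusted p = 3.79e-04). Markers of T and NK cells were higher in the same libraries, and Ifng, the gene of interferon-gamma itself and a member of that list, went from 0.102 ± 0.176 to 0.622 ± 0.592 CPM without passing (edgeR adjusted p = 0.747).

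Genes of antigen presentation were higher as groups, in lists that share members with the interferon-gamma list. B2m, Tap1, Tap2 and Tapbp of class I and Ciita of class II belong to both, so these tests are not independent. Of the 18 tested genes of MHC class I presentation 17 had a positive fold change, the median was 0.75, and Tap1 alone rose when adjusted over the list alone. The camera test of limma gave an adjusted p of 1.30e-08, and an adjusted p of 0.270 with an estimated correlation. An exact permutation test of the mean log2 CPM of this list gave p = 0.0571. The 12 genes of MHC class II presentation had a median of 0.60 and 10 positive values, and none passed when adjusted over the list alone. Their camera test (limma) gave an adjusted p of 0.00798, and an adjusted p of 0.432 with an estimated correlation. For class II the exact permutation p of the mean log2 CPM was 0.171. The class II call was lost without Dicer1-deleted replicate 1 (adjusted p = 0.0562), Dicer1-deleted replicate 2 (0.0806, median 0.21) or control replicate 3 (0.0504).

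The lists of macrophage polarization moved in opposite directions. The M1-like list, genes of macrophages activated by interferon-gamma or bacterial products, had a median log2 fold change of 0.78 over 21 genes, and 7 members rose when adjusted over the list alone. These were Cxcl9, Cxcl10, Cxcl11, Cd38, Gpr18, the formyl peptide receptor Fpr2 (from 20.8 ± 4.81 to 110.3 ± 76.8 CPM) and the integrin Itgax (from 24.4 ± 12.1 to 111 ± 43.5 CPM). Cxcl9, Cxcl10, Cxcl11 and Nos2 also belong to the interferon-gamma list, and Cd80 and Cd86 to the MHC class II list. The tests of these lists are therefore not independent. The camera test of the M1-like list (limma) gave an adjusted p of 8.38e-07, and an adjusted p of 0.270 with an estimated correlation. The exact permutation p of its mean log2 CPM was 0.0571. Nos2, a classical member of the list, had a log2 fold change of -0.52 ± 0.90 (SE) and did not pass. Of the 21 members 15 had a positive fold change. Among others that did not pass, Tnf, Il6, Il12b, Il15, Il1a and Il23a were at 0.29, -0.07, 0.08, -0.19, -0.58 and -1.46, and Il1b at 1.14.

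The M2-like list, genes of interleukin 4-activated and resident macrophages, had a median of -1.43 over 32 genes, with 23 negative values. Of its members 11 fell and none rose when adjusted over the list alone. The matrix protein fibronectin (Fn1) fell from 832 ± 260.3 to 193 ± 61.9 CPM (SD, n = 4 and 3), the transcription factor Klf4 from 163 ± 32.6 to 77.3 ± 4.98 CPM, and the secreted protein Retnla from 19.4 ± 16.3 to 2.20 ± 0.458 CPM. Lyve1, the folate receptor Folr2, Timd4, the chemokines Ccl17 and Ccl22, and the lectins Cd209a, Cd209f and Cd209g were the other members that fell. The Cd209 genes are close copies that can share reads. Arg1 and Mrc1, common markers of this state, had log2 fold changes of -0.85 ± 0.42 and -0.25 ± 0.41 (SE) and did not pass, and Il10 had 0.98 ± 0.41. The camera test of limma gave an adjusted p of 4.72e-07, and an adjusted p of 0.432 with an estimated correlation. The exact permutation p of the list's mean log2 CPM was 0.0857.

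**Figure D2:**
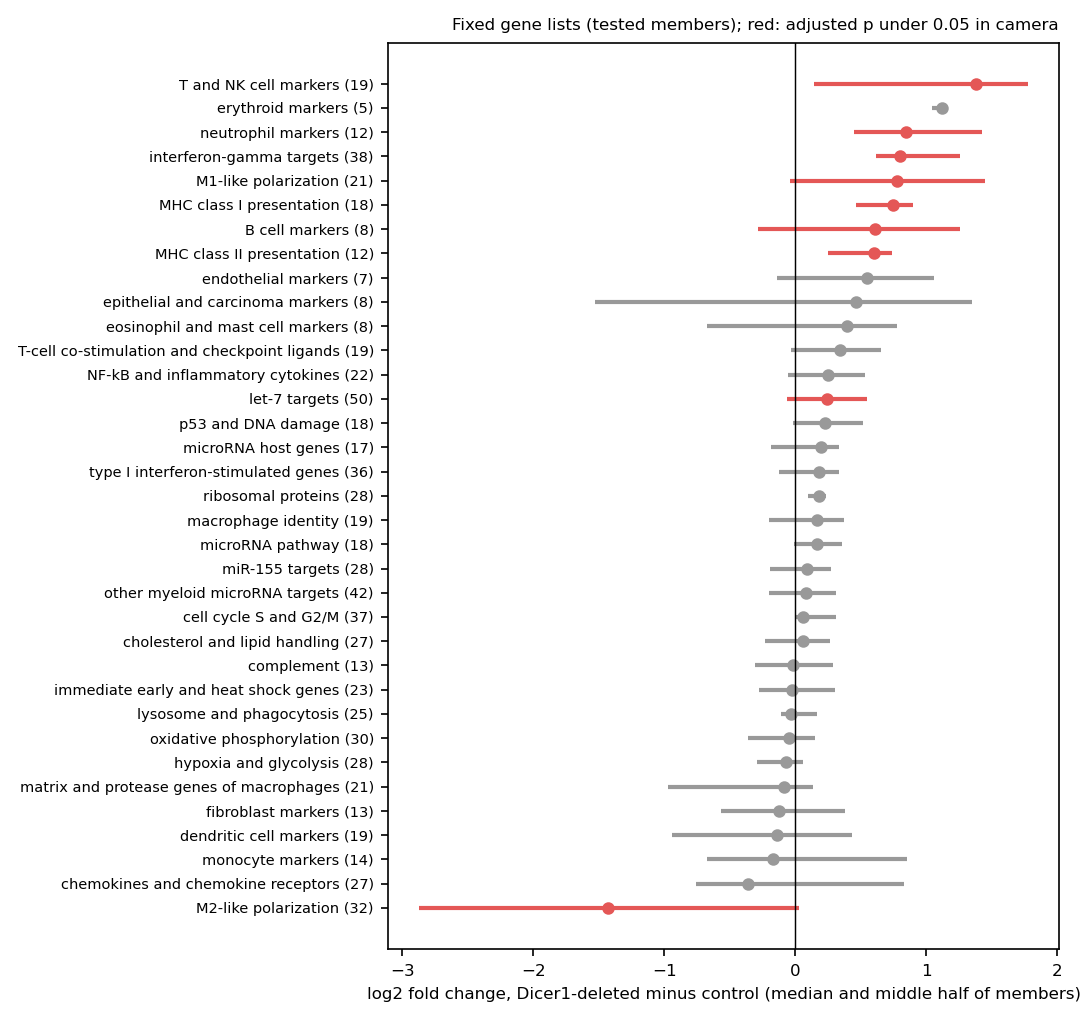
Median log2 fold change (points) and the middle 50% of members (lines) of the 35 fixed gene lists, Dicer1-deleted minus control (horizontal axis), with tested members in brackets. The 9 lists in red had an adjusted p under 0.05 in camera with the preset correlation, from T and NK cell markers at 1.38 to the M2-like list at -1.43.

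Markers of T and NK cells were higher at low levels. The 19 tested markers had a median log2 fold change of 1.38, and camera (limma) gave an adjusted p of 0.00308, with an adjusted p of 0.270 with an estimated correlation. Their mean log2 CPM was between -0.451 and 0.63 in the Dicer1-deleted libraries and between -1.38 and -0.588 in the control libraries. An exact permutation test of this mean gave a two-sided p of 0.0286, the smallest that 3 against 4 libraries allow, and 0.375 when adjusted over the 35 lists, of which none passed this test. Cd2, an adhesion protein of T and NK cells, was the member that passed when adjusted over the list alone, and it fell, from 5.50 ± 1.65 to 1.69 ± 0.319 CPM (SD, n = 4 and 3). Nkg7, a protein of cytotoxic granules, rose in DESeq2 (adjusted p = 0.0410), from 1.18 ± 0.579 to 3.96 ± 1.81 CPM. Without Dicer1-deleted replicate 1 the list had an adjusted p of 0.140, and with read pairs counted instead of reads it had a median of 0.61 and an adjusted p of 0.0696.

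Markers of B cells and neutrophils were higher in parts of their lists. Of 8 tested B cell markers 3 rose when adjusted over the list alone, the signaling adaptor Bank1 from 6.74 ± 1.21 to 26.9 ± 11.4 CPM, the receptor chain Cd79b from 7.37 ± 1.71 to 18.6 ± 7.56 CPM and the immunoglobulin mu chain Ighm from 48.7 ± 14.3 to 115 ± 19.6 CPM (SD, n = 4 and 3). Ighm lies 8.73 Mb from Dicer1. Ms4a1, the gene of CD20, was at 0.23 ± 0.79 (log2 fold change, SE). The antibody genes Igkc and Jchain pointed down without passing, at -2.36 ± 1.28 and -1.85 ± 1.25, Igkc from 5.70 ± 6.79 to 1.10 ± 1.57 CPM and Jchain from 1.69 ± 1.62 to 0.464 ± 0.641 CPM. The list's median was 0.61 and its adjusted p in camera (limma) 0.0181, with an adjusted p of 0.432 with an estimated correlation. Its mean log2 CPM was 1.62 in Dicer1-deleted and 1.44 in control libraries, with an exact permutation p of 0.771. The B cell call was lost without Dicer1-deleted replicate 1, 2 or 3 (adjusted p = 0.779, 0.0709 and 0.239, medians -0.02, 0.50 and 0.14) and without control replicate 4 (0.0853), and with no count filter (0.210, median 0.25). The 12 neutrophil markers had a median of 0.85 (limma, camera adjusted p = 0.00798, and an adjusted p of 0.332 with an estimated correlation). The exact permutation p of their mean log2 CPM was 0.0857. The collagenase Mmp8 was the member that rose when adjusted over that list alone, from 47.2 ± 15.2 to 119 ± 24.3 CPM, while S100a8, an abundant neutrophil transcript, was at 9.63 ± 9.60 CPM in Dicer1-deleted and 9.09 ± 4.87 CPM in control libraries. Without Dicer1-deleted replicate 2 the neutrophil list had an adjusted p of 0.107, and with the 10 CPM filter 0.139.

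Targets of let-7 microRNAs were higher by a small amount. The 50 tested members of the let-7 target list had a median log2 fold change of 0.24, with 35 positive values, and none passed when adjusted over the list alone. Camera (limma) gave an adjusted p of 0.00678, and an adjusted p of 0.432 with an estimated correlation. An exact permutation test of the list's mean log2 CPM gave p = 0.229. Hmga2, a well-known let-7 target, had a log2 fold change of -0.44 ± 0.32 (SE). Without Dicer1-deleted replicate 3 the list had an adjusted p of 0.114. The miR-155 targets (28 genes, median 0.09), other myeloid microRNA targets (42 genes, 0.08), microRNA pathway genes (18 genes, 0.16) and microRNA host genes (17 genes, median 0.20, mean -0.03) had adjusted p-values of 0.708, 0.798, 0.206 and 0.754. The microRNA pathway list passed without Dicer1-deleted replicate 2 (median 0.32, adjusted p = 0.00616), with the L code as covariate (0.29, adjusted p = 0.0382) and with quality weights (0.35, adjusted p = 0.0123).

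Genes with seed sites for let-7a in their 3' UTR were shifted in the same direction. A seed site is a match to bases 2 to 8 of a microRNA, and 1261 of 12127 tested genes with a 3' UTR held the site CTACCTC. Their log2 fold change was higher by a median of 0.055 than that of genes matched on UTR length and expression. The two-sided permutation p over genes was 1e-05, the smallest the permutations can give, and the adjusted p over 26 microRNAs was 2.6e-04. Sites of 4 other microRNAs among the 20 of myeloid cells passed this permutation test, with shifts of 0.040 for miR-125b (adjusted p = 0.00065), 0.028 for miR-23a (0.00546), 0.022 for miR-34a (0.0408) and 0.020 for miR-24 (0.0497). With all libraries none of the 6 microRNAs of other tissues passed, but without control replicate 2 miR-133a, a muscle microRNA, did, with a shift of 0.0506 (adjusted p = 0.00364). Among the myeloid microRNAs that did not pass were miR-155, miR-142a-3p, miR-223, miR-21a and miR-146a, with shifts of -0.0207, 0.0135, -0.00792, 0.00115 and -0.00598. Genes are not independent replicates, so these p-values hold across genes and not across animals. The let-7a shift passed with each replicate left out in turn (0.039 to 0.066), and without matching it was 0.0385 (adjusted p = 0.0559). Without Dicer1-deleted replicate 2 the shifts of miR-125b, miR-34a and miR-24 were 0.00143, -0.000454 and -0.00339, and without Dicer1-deleted replicate 1 that of miR-23a was -0.000289.

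In the edgeR fit the lists of macrophage functions did not pass as a whole, while single members did when adjusted over their list alone. In the chemokine list (27 genes, median -0.36, adjusted p = 0.798) Cxcl9, Cxcl10 and Cxcl11 rose and Cxcl13, Ccl17, Ccl22 and Ccr7 fell. In the lysosome and phagocytosis list (25 genes, median -0.03, adjusted p = 0.798) Axl, a receptor for dying cells, rose from 49.7 ± 13.6 to 127 ± 20.3 CPM (SD, n = 4 and 3), and Ctsk, Atp6v0d2 and Mfge8 fell. In the complement list (13 genes, median -0.02, adjusted p = 0.708) Vsig4, a complement receptor of resident macrophages, fell from 6.86 ± 3.81 to 0.167 ± 0.190 CPM. In the matrix and protease list (21 genes, median -0.09, adjusted p = 0.0621) Fn1, Timp1 and Timp2 fell and Mmp8 rose. In the list of T-cell co-stimulation and checkpoint ligands (19 genes, median 0.34, adjusted p = 0.0584) the cytokine gene Il27 rose from 1.11 ± 0.401 to 5.57 ± 3.25 CPM. The matrix list passed in DESeq2 (adjusted p = 0.0163) and without control replicate 1 or 2 (0.0392 and 0.0326). The co-stimulation list passed in DESeq2, in limma-voom, with no count filter and with the L code as covariate (adjusted p = 0.0346, 0.0318, 0.0328 and 0.0335, medians 0.37, 0.27, 0.38 and 0.35). It also passed with quality weights, with the newer quasi-likelihood and with camera on log2 CPM (0.0490, 0.0473 and 0.0359), and without Dicer1-deleted replicate 3 (0.019) or control replicate 2 or 4 (0.0466 and 0.0167). In the macrophage identity list (19 genes, median 0.17, mean -0.02, adjusted p = 0.902) the lysozymes Lyz1 and Lyz2 fell, Lyz2 from 139 ± 50.6 to 57.0 ± 8.97 CPM. Lyz1 and Lyz2 are close copies that share reads, and the Cre sits in the lysozyme M locus in both groups. Adgre1, the gene of F4/80, was at 660.8 ± 420.0 CPM in Dicer1-deleted and 567 ± 162 CPM in control libraries.

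Lists of general cell states did not pass in the edgeR fit of all libraries, and several depended on single libraries or on the method. The adjusted p-values were 0.119 for NF-kB and inflammatory cytokines (22 genes, median 0.25), 0.249 for the cell cycle (37 genes, 0.06), p53 and DNA damage (18 genes, 0.23) and hypoxia and glycolysis (28 genes, -0.07), and 0.358 for oxidative phosphorylation (30 genes, -0.05). They were 0.797 for cholesterol and lipid handling (27 genes, 0.06), where Nr1h3 and Pparg, nuclear receptors of lipid metabolism, rose in DESeq2 (adjusted p = 0.0487 and 0.0184), and 0.797 for immediate early and heat shock genes (23 genes, -0.03). The ribosomal protein list (28 genes, median 0.18) had an adjusted p of 0.182. Without Dicer1-deleted replicate 2 its median was -0.41 (adjusted p = 1.03e-04), and without Dicer1-deleted replicate 1 or 3 or control replicate 1 or 2 it was 0.34, 0.45, 0.32 and 0.33 (adjusted p = 0.00742, 1.55e-04, 0.0146 and 0.0326). Also without Dicer1-deleted replicate 2, the cell cycle list passed with a median of 0.32 (adjusted p = 3.01e-05), the hypoxia and glycolysis list with -0.33 (2.24e-04) and the oxidative phosphorylation list with -0.40 (0.00642). The NF-kB list passed without Dicer1-deleted replicate 3 (adjusted p = 0.0145) or control replicate 4 (0.00891), and the p53 list without control replicate 3 (0.033) or with the L code as covariate (0.0404, median 0.45). With quality weights and all libraries the cell cycle, p53, hypoxia, oxidative phosphorylation and ribosomal lists passed (adjusted p = 0.00235, 0.0383, 0.00183, 0.00991 and 0.00183), with medians of 0.30, 0.36, -0.25, -0.35 and -0.32.

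Markers of other cell types were uneven. In the monocyte list (14 genes, median -0.17, mean 0.15, adjusted p = 0.865, with the test pointing up) Treml4 rose and Fn1 fell when adjusted over the list alone, and without control replicate 3 the list passed with a median of 0.52 (adjusted p = 0.0239). In the dendritic cell list (19 genes, median -0.14, adjusted p = 0.754, again with the test pointing up) Xcr1, a chemokine receptor of cross-presenting cells, rose from 0.849 ± 0.472 to 4.47 ± 1.59 CPM (SD, n = 4 and 3), Batf3 and Htr7 rose, and Ccr7 and Cd209a fell. Pecam1 rose from 8.20 ± 4.07 to 48.6 ± 18.3 CPM in the endothelial list (7 genes, median 0.55, adjusted p = 0.249). Spint1 and Sfn rose and Krt7 fell in the epithelial and carcinoma list (8 genes, median 0.46, mean -0.06, adjusted p = 0.408). The eosinophil and mast cell (8 genes, median 0.40), fibroblast (13 genes, -0.12) and erythroid (5 genes, 1.12) lists had adjusted p-values of 0.902, 0.798 and 0.319. Erythroid transcripts made up 580.2 CPM of Dicer1-deleted replicate 2 and 28.1 to 229.7 CPM of the other libraries, and without that replicate the erythroid median was -1.42 (adjusted p = 0.00477), and with quality weights it was -0.95 (adjusted p = 0.0382).

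The libraries also differed in ways that the genotype does not follow. The first principal component of log2 CPM, with 36.5% of the variance, placed Dicer1-deleted replicate 2 at 134.2 and all others between -66.2 and 22.2. The second, with 23.04%, did separate the groups, with the Dicer1-deleted libraries at -61.7, -26.3 and -57.6 and the control libraries between 4.77 and 71.3. Dicer1-deleted replicate 2 had a mean correlation of 0.901 with the other libraries, against 0.928 to 0.935 for each of those. For transcripts shorter than 1000 nt its median log2 ratio to the mean of the other 6 libraries was 0.77, against 0.33 and 0.35 in control replicates 1 and 2 and -0.40 to -0.23 in the remaining 4. It had no read on 536 tested genes, against 153 to 306, and genes annotated as ribosomal RNA, mitochondrial ones included, took 2.93% of its reads, against 0.934% to 2.35%.

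**Figure D3:**
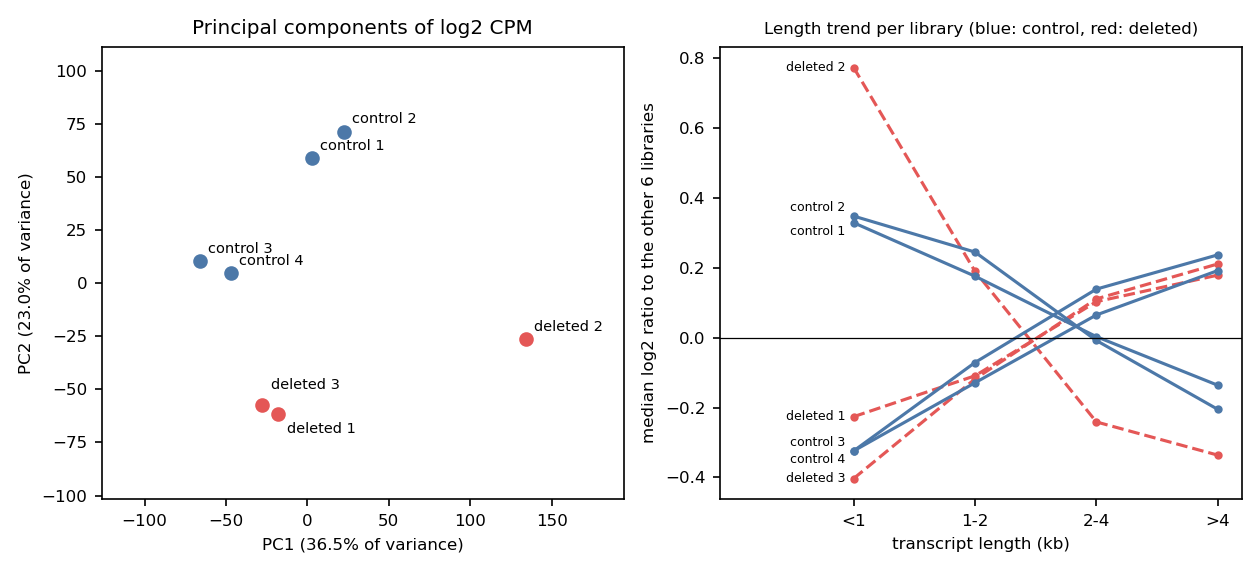
Left, the first and second principal components of log2 CPM, with a point per library (blue, control; red, Dicer1-deleted). Right, the median log2 ratio of each library to the mean of the other 6 (vertical axis) for genes grouped by transcript length in kb (horizontal axis). Dicer1-deleted replicate 2 and control replicates 1 and 2 fall with length, and the other 4 libraries go the other way.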

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

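Of 82 values examined in the 4 control libraries, 2 had a library far from the others, where chance gives about 1 in 20. For the hypoxia and glycolysis list, control replicate 4 had a mean log2 CPM of 7.25, against 6.66 to 6.73 in the other 3 control libraries. Its gap to the nearest was 0.888 of the group's range. For the B cell markers, control replicate 4 had a mean log2 CPM of 0.51, against 1.69 to 1.83, a gap of 0.894 of the range. Without this library the B cell list had an adjusted p of 0.0853 in camera (limma). No cause was tested for either value.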

How the results depend on the processing

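Read pairs, multiply placed reads, length correction, quality weights, edgeR's newer quasi-likelihood, DESeq2 without Dicer1-deleted replicate 2, camera on log2 CPM and the site test without each library were chosen after seeing the data. Of 131 alternative values of the 7 counts and levels, 71 stayed the same, 21 became larger calls, 37 smaller and 2 moved. Where no cause is named below, the cause was not tested. The 4 changed genes (1 higher, 3 lower) became 405 (150 and 255) in DESeq2, 338 (111 and 227) in DESeq2 without Dicer1-deleted replicate 2, 80 (37 and 43) with quality weights, 42 (24 and 18) with no filter, 8 (3 and 5) with length correction and 7 (3 and 4) with the newer quasi-likelihood. They became 2 (0 and 2) in limma-voom, 1 (0 and 1) with the 10 CPM filter, which tests fewer genes, and 0 (0 and 0) with the L code as covariate (1088 at an unadjusted p under 0.05) and with glmTreat (444). With fewer samples, leaving out each replicate gave 0 to 3 (0 to 1 higher, 0 to 2 lower). Dicer1 passed at -1.14 in DESeq2 and -1.09 without Dicer1-deleted replicate 2. Of the 35 lists, 9 passed, 0 with an estimated correlation or fry, 18 with quality weights (all 9 among them) and 15 in DESeq2 without Dicer1-deleted replicate 2 (7 of the 9 among them). Calls lost with an estimated correlation and fry had unchanged medians, 0.80 (interferon-gamma), 0.60 (MHC class II), 0.75 (MHC class I), 0.78 (M1-like), -1.43 (M2-like), 0.24 (let-7), 0.85 (neutrophil), 1.38 (T and NK) and 0.61 (B cell). Also lost were MHC class II (0.22) and neutrophil markers (0.66) in DESeq2 without Dicer1-deleted replicate 2, neutrophil markers with the 10 CPM filter (0.72), T and NK markers with read pairs (0.61) and B cell markers with no filter (0.25). Leaving out each replicate gave medians of 0.21 to 0.85 for MHC class II, 0.17 to 0.36 for let-7 targets, 0.61 to 1.20 for neutrophil, 0.98 to 1.45 for T and NK and -0.0153 to 0.90 for B cell markers. The ribosomal protein median turned to -0.32 with quality weights and -0.40 in DESeq2 without Dicer1-deleted replicate 2 (-0.41 to 0.45 leaving out each replicate), and the erythroid median to -0.95 and -1.41 (-1.42 to 1.67). The 5 called microRNA sites became 2 with 8mer sites, 1 with no matching, 2 with the shortest 3' UTR and 2 to 5 leaving out each replicate, where shifts ranged from -0.000289 to 0.0491 for miR-23a, -0.00339 to 0.0440 for miR-24 and -0.000454 to 0.0469 for miR-34a. The first principal component held 41.2% with a prior count of 5 and 39.7% with the 500 most variable genes, where it separated the groups. Of the alternatives for list medians the call was unchanged in 859 of 940, for named genes in 830 of 974 and for site shifts in 236 of 260. A result uncalled in both fits counted as unchanged whatever its value or sign, so these counts do not measure how far the values moved. At this spread edgeR recovered 1 of 50 simulated 2-fold changes, so changes of that size would mostly have been missed in such a simulation.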

Other observations

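The tests of depth, other cell types and length correlation in Dicer1-deleted replicate 2, of T and NK markers, with the length trend removed and of the split with 3224 genes were chosen only after the results were seen. Across the 35 splits of the 7 libraries into 3 and 4, chance could not be excluded at 5% for the results counted in this way, given next. In edgeR 2 splits, the real one included, called as many genes (4, highest other 3224), 3 as many higher genes (1, highest other 1621) and 2 as many lower genes (3, highest other 1603). In DESeq2 2 splits called as many (405, highest other 4496). For the lists 25 splits brought as many past the threshold (9, highest other 19), and 3 gave the interferon-gamma list a p as small (20.7 as -log10 p, highest other 27.2). For the let-7a sites 2 splits gave a shift as far from 0 (0.0568, highest other 0.0579). Here the shift was the bin-adjusted median of genes with a site less that of genes without, from mean log2 CPM. Of the other called sites, 15 splits gave as large a shift for miR-125b and miR-34a, 19 for miR-24 and 20 for miR-23a. With the length trend removed 2 splits called as many genes in edgeR (8, highest other 1328). The split with 3224 genes set Dicer1-deleted replicate 2 and control replicates 1 and 2 against the other 4 libraries, and its count, far above the 4 of the real split, points to a structure of the samples. It follows neither the genotype nor the L code of the titles.

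Dicer1-deleted replicate 2 stood apart from the other libraries, and together with control replicates 1 and 2 it had relatively more reads on short transcripts. The tables argue against lower depth, as its 45.4 M reads lay within the range of the others. Marker lists of red blood cells and other cell types together held 0.323% of its reads, against 0.232% to 0.438% in the other libraries. Its erythroid transcripts, at 580.2 CPM, were the highest of the 7 libraries. The share counts marker genes only, so RNA of red blood cells and other cell types stays open. The tables also argue against the length trend as the whole cause. The gap of this library's mean correlation to the next library was 0.0269 before and 0.0233 after the trend was removed. A length bias may account for a part, and stays open because the correlation across genes of length and log2 ratio was -0.272 in this library and -0.276 in control replicate 2, which did not stand apart, and because the count for that split was 3224 before and 1328 after removing the trends. A biological difference between the tumors was not tested.

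Genes near Dicer1 on chromosome 12 may differ between the groups through strain variants linked to the conditional allele. Within 10 Mb of Dicer1, 16 of 121 tested genes (13.2%) had an unadjusted p under 0.05, against 1242 of 15201 other genes (8.17%), an odds ratio of 1.71 (95% interval 0.941 to 2.92, Fisher's exact p = 0.0642). Without Dicer1-deleted replicate 2 the odds ratio was 1.87 (Fisher's exact p = 0.0187). The interval includes both no excess and a sizeable one, so linked variants and the deletion cannot be told apart for these genes, among them Asb2 (log2 fold change 5.51), Serpina3g, Crip2 (-2.08), Ahnak2 (-1.67) and Ighm. Neighboring genes are not independent, which the test ignores.

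Whether the higher T and NK cell markers in the Dicer1-deleted libraries may come from more T-cell RNA among the sorted cells stays open. The mean log2 level of 6 T-cell receptor complex genes was higher by 1.21 in the Dicer1-deleted group (exact permutation p = 0.0286), but all 6 belong to the list that was higher, so this restates the observation and is no independent evidence. Cd3g went from 0.445 ± 0.306 to 1.53 ± 0.208 CPM (SD, n = 4 and 3), while Cd2 fell and Cd4 was at -1.65 ± 0.99 (log2 fold change, SE), and a sort for F4/80 would remove most T cells. A lower share of macrophages would raise markers of every other cell type, and the T and NK score less the fibroblast score was higher by 1.06 (exact permutation p = 0.114), so it cannot be told apart with this few libraries. Whether more T cells entered these tumors was not tested.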
